A study of Mus musculus with 16 samples.

How the data were processed

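RNA from mouse dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, was measured on 16 Affymetrix arrays. Per the labels, the first screen used ganglia dissected at embryonic day 14.5 and pooled over embryos. It had 2 arrays of Bax null ganglia (replicates A and B) and 2 arrays of ganglia null for both NGF and Bax (replicates A and B). NGF, nerve growth factor, is a survival factor of nociceptive neurons, and loss of the death effector Bax keeps neurons without NGF alive. The second screen used wild-type ganglia from 4 litters at embryonic day 13.5, grown as explants on poly-D-lysine and laminin for 48 h with 50 ng/ml of NGF or of NT3 (neurotrophin 3). It had 2 cultures per group and 3 chips of different probe sets per culture, so 12 arrays in all. The labels give a C57BL/6 background, mixed sex, RNA from a column kit, 1 round of amplification from an oligo-dT primer and biotin labelling. They name replicates by letter or number without saying whether the samples came from separate litters or dissections. The p-values measure the spread between these samples, which can be in part or wholly technical.

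The deposited values are linear signal intensities per probe set, made by the authors with Affymetrix GCOS 1.4 and MAS5 per the submitters' processing notes. In the deposited intensity tables the mean of each array without its highest and lowest 2% of values was 150, so each array had been scaled on its own. Other steps of the authors' processing are not given in the sources used here. Median intensity lay between 46.2 and 51.1 on the 4 in vivo arrays and between 52.9 and 81.9 on the 12 explant arrays. The number of arrays limits the precision of every value. Probe sets were named from the platform annotation tables, with symbols looked up by gene identifier in a RefSeq table of assembly GRCm38.p6 that was used only for names and for the order of genes. Of the 45037 in vivo probe sets, 34945 had 1 symbol, 932 had several and 9160 had none. On chips 1, 2 and 3 of the explants, 10833, 10581 and 7717 probe sets had 1 symbol, out of 12422, 12411 and 11868. No probe set with several symbols was named. No probe set carried the names Ngf, Bax, Ntrk1 or Calca in the annotation used here, so these genes were not analysed here, and the deleted genes could not serve as a check of the labels.

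Values were tested as log2(signal + 16), so a log2 fold change understates the change of weakly detected genes. Control probe sets were left out, 64 in vivo and 66 on each explant chip. The 60% of probe sets with the highest mean were tested, 27022 in vivo and 22021 in the explants (7453, 7447 and 7121 on chips 1 to 3). The lowest mean log-scale signal tested corresponded to an intensity of 30.04 in vivo and of 37.8, 52.0 and 38.6 on chips 1 to 3. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with NGF minus without NGF, where without NGF means NGF,Bax null in vivo and NT3 in the explants. The explant chips were fitted separately and Benjamini-Hochberg adjustment ran over the 3 chips together, with a threshold of 0.05. Errors of log2 fold changes are the standard errors (SE) of limma in the fit without a block. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

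The tests, the filter, 22 gene lists, the rule for naming genes and the other settings listed at the end were set before the data were examined. The joint fit of both screens and the tests of other explanations were not among them. Genes are named by this rule: the manipulated genes, the neurotrophin receptors and Hoxd1 whatever their values; the 10 highest and 10 lowest fold changes among calls with 1 symbol whose arrays did not overlap between groups; up to 4 members of each list with the smallest p; and genes called in both screens. A gene was read from 1 probe set, taken from the lowest-numbered chip, preferring identifiers without _x_at, and then by the highest mean. Named in addition, after their values were seen, were genes with an adjusted p between 0.05 and 0.1 in vivo, genes called in the explants with the culture number as a block, genes with an unadjusted p under 0.05 in both screens, the Ptgds probe set that passed, other probe sets with large changes, Srebf2 as the member of its list below 0, genes that differed between the screens, and the genes of the neurogenesis list and around Ngf. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares the genes of a list with all other genes. Benjamini-Hochberg adjustment ran over the 21 lists with at least 5 measured genes. The list of sex-linked genes had fewer and was not tested. Each list was also tested with the correlation estimated from the arrays, and no list passed in that form in either screen. The difference between the screens was tested over 10129 genes in a joint limma fit with a term for the difference of the NGF effects.

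Whether the replicate letters or numbers pair the arrays was checked from the correlation of same-named arrays' deviations from their group means. It was -0.134 in vivo, and 0.572, 0.343 and 0.307 on explant chips 1, 2 and 3. On chip 1 of the explants, arrays of the same culture number correlated at 0.955 and 0.969, and arrays of different numbers at 0.915 to 0.927. In vivo the 2 Bax null arrays correlated at 0.975 and the 2 NGF,Bax null arrays at 0.982. Arrays of different genotypes correlated at 0.969 to 0.982, so the in vivo arrays did not group by genotype. Bax null A was the array least like the others. No label says what a shared culture number stands for. Because the arrays split by it, the number was treated as a batch evident from the values, and explant results are given with it as a block in limma and within each number as well. The actin control ratio of 3' to 5' signal, a measure of RNA integrity, was 1.72, 1.56 and 1.78 on the 3 chips of NT3 culture 1 and between 1.15 and 1.38 on the other explant arrays.

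The fits were tested on simulated data with log2 changes planted in 200 probe sets over 5 simulations. For the in vivo comparison, run on 27022 probe sets, 70.3% of planted changes of 1 and 99.6% of planted changes of 2 were recovered, and 9.71% of calls were false. For the explants, run on 22021 probe sets with the culture number effect of the files, the fit without a block recovered 0% of changes of 1 and 5.09% of changes of 2. With the block these shares were 57.6% and 94.9%, with 13.5% of calls false. With the block and no number effect in the simulated arrays, 30.8% of calls were false. Planted shifts of the cholesterol list, 0.3 in vivo and 0.7 in the explants, were found by camera with the preset correlation at adjusted p = 1.02e-08 and 2.72e-20, with 0 of 20 other lists called, and were missed with the estimated correlation at adjusted p = 0.958 and 0.614. The noise of these arrays was drawn independently for each probe set, so false list calls caused by correlated genes could not show. In the joint fit on 10129 genes, 95 of 100 planted differences of 2 and 100 of 100 of 4 were recovered, with 9 false calls over both. These simulated arrays held no culture number effect, so the shares do not show what the joint fit recovers from the real arrays.

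Alternatives were a pseudocount of 1 or 64, no filter or the highest 40% of probe sets, quantile or median scaling between arrays, and eBayes without a trend. Further ones were the replicate letter or number as a block, each replicate left out in turn, a rule of at least 2-fold in all 4 pairs of arrays, adjustment within each chip, the mean over a gene's probe sets and the estimated correlation.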

Results

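Gene expression was compared between dorsal root ganglia that had NGF and ganglia that did not, in 2 screens that share no array. In vivo, 2 arrays of Bax null ganglia at E14.5 were set against 2 arrays of ganglia lacking both NGF and Bax. In culture, ganglia of E13.5 grown for 48 h with NGF were set against ganglia grown with NT3, with 2 cultures per group. NT3 itself acts on sensory neurons, so the second contrast is NGF against another neurotrophin. Values are MAS5 signals, and every fold change is given as with NGF minus without, n = 2 per group.

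The in vivo comparison asked which transcripts differ with NGF in ganglia whose neurons were kept alive by loss of Bax. The RNA came from whole ganglia, so the cell type behind a change was not tested. With NGF present, the homeobox transcription factor gene Hoxd1 rose by 2.27 on the log2 scale (SE 0.17, n = 2), from a mean signal of 54.3 to 325.6. Bnc1, which encodes the zinc-finger protein basonuclin 1, rose by 1.96 (SE 0.13), from 143.5 to 604.8. The T-box transcription factor gene Tbx18 fell by 1.77 (SE 0.18), from 213.3 to 51.3, and Cdkl4, a gene of the cyclin-dependent kinase-like family, fell by 1.58 (SE 0.15), from 267.0 to 78.5. As lists, genes of cholesterol synthesis were higher with NGF, and genes of fibroblasts and of cell proliferation were lower. None of the 3 lists passed camera with an estimated correlation (adjusted p = 0.542 each, Benjamini-Hochberg), a form that also missed the planted shifts in simulated arrays. These 4 genes were the only ones that passed. In limma with Benjamini-Hochberg adjustment they stood at adjusted p = 0.00593 for Hoxd1, 0.00425 for Bnc1, 0.0292 for Tbx18 and 0.0261 for Cdkl4. In each of them both arrays of one group lay above both of the other. A second Tbx18 probe set stood at -0.83 (adjusted p = 0.398) and a second Cdkl4 probe set at -0.07 (adjusted p = 0.937) in the same limma fit with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 2180 probe sets, where chance would give 1351. All 4 calls were kept with any 1 array left out. The count of calls rose to 164 without Bax null A, 2103 without Bax null B, 30 without NGF,Bax null A and 16 without NGF,Bax null B. With Bax null B left out, the group with NGF was Bax null A alone, the array least like the others (correlations of 0.969 to 0.975). Without the filter on low values, or in eBayes without a trend, no probe set passed. With the replicate letter as a block, which the labels do not pair, Tbx18 and Cdkl4 did not pass (limma adjusted p = 0.0583 and 0.0719, Benjamini-Hochberg). The 40% with the highest mean held 10 calls.

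**Figure D1:**
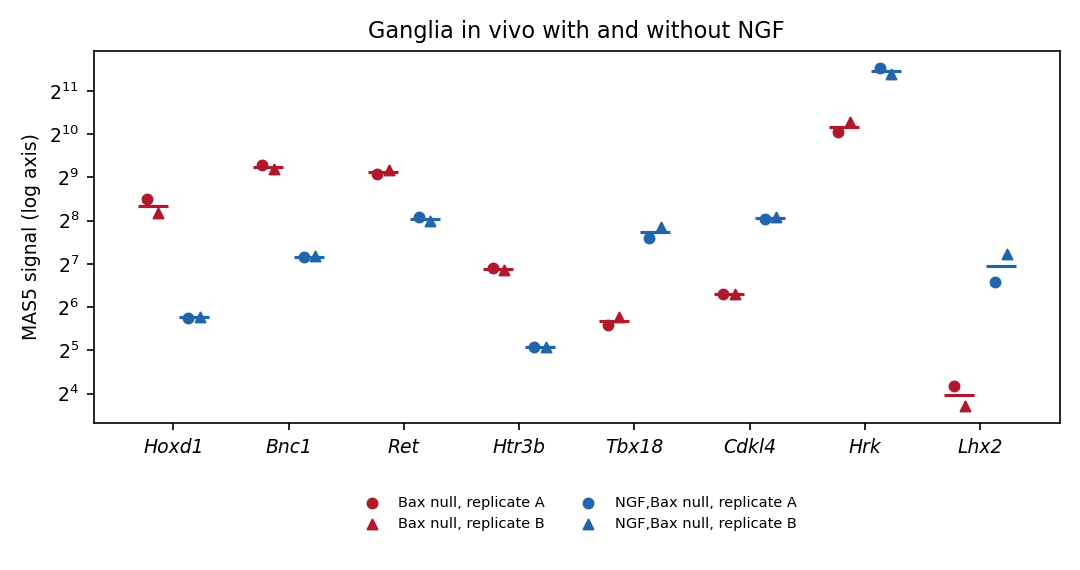
MAS5 signal on a log axis of 8 genes in ganglia at E14.5, with red for Bax null and blue for NGF,Bax null ganglia, circles for replicate A, triangles for replicate B and bars for the mean of 2 arrays. For each gene both red points lie on the same side of both blue points; of these genes only Hoxd1, Bnc1, Tbx18 and Cdkl4 passed the test.

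Another 12 probe sets had an adjusted p between 0.05 and 0.1 and did not pass. Those with a gene name included Ret at 1.05 (SE 0.13), the receptor tyrosine kinase of GDNF family ligands, Htr3b at 1.43 (SE 0.19), a serotonin receptor subunit. Rgs7 stood at 1.01 (SE 0.13) and Rgs7bp at 0.97 (SE 0.13), a regulator of G protein signalling and its binding protein. Lower values were found for Lhx2, a LIM homeobox gene, at -2.11 (SE 0.25; its mean signal with NGF, 15.5, lay under the lowest mean tested), and for Hrk, a death gene of the Bcl-2 family that neurons are known to induce on NGF withdrawal, at -1.29 (SE 0.16). Their limma adjusted p with Benjamini-Hochberg adjustment was 0.0702 for Ret, Lhx2 and Hrk, 0.0801 for Htr3b, 0.0804 for Rgs7 and 0.0904 for Rgs7bp. Among the neurotrophin receptor genes, Ntrk2 stood at -0.19 (SE 0.13, adjusted p = 0.705), Ntrk3 at -0.30 (SE 0.17, adjusted p = 0.657) and Ngfr at -0.05 (SE 0.16, adjusted p = 0.935), none past the threshold.

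Cholesterol synthesis genes were higher with NGF in vivo as a list. Of 20 measured members 19 lay above 0, with a median log2 fold change of 0.27 and an adjusted p of 1.64e-06 in camera with Benjamini-Hochberg adjustment over the lists (adjusted p = 0.542 with an estimated correlation). The median was 0.18 without Bax null A, the lowest of the other settings, and the adjusted p lay between 3.39e-07 and 2.27e-04 over 13 of them. No member passed over all genes and 1 did when adjusted over the list alone, Idi1 at 0.59 (SE 0.14), the isopentenyl diphosphate isomerase. Idi1 was not called with the replicate letter as a block. Pmvk stood at 0.54, Sc5d at 0.37 and Msmo1 at 0.37, while Srebf2, which encodes a transcriptional activator of the pathway, stood at -0.30.

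Fibroblast and mesenchyme genes and proliferation genes were lower with NGF as lists. Of 28 fibroblast genes 22 lay below 0 (median -0.18, camera adjusted p = 9.25e-04 with Benjamini-Hochberg adjustment, adjusted p = 0.542 with an estimated correlation). Among them were Foxc1 at -0.50, Col1a1 at -0.49 and Lox at -0.49. Of 35 proliferation genes 28 lay below 0 (median -0.17, camera adjusted p = 9.25e-04 with Benjamini-Hochberg adjustment, adjusted p = 0.542 with an estimated correlation). Among them were Top2a at -0.55, Bub1b at -0.41 and Cdc20 at -0.40. No member of either list passed over all genes, and none did when adjusted over the list alone. The proliferation list did not pass without Bax null B (adjusted p = 0.0713) or without NGF,Bax null B (adjusted p = 0.0788). Over 13 other settings its camera adjusted p with Benjamini-Hochberg adjustment lay between 5.91e-05 and 0.0788. Markers of other cell types in the tissue did not pass as lists by camera with Benjamini-Hochberg adjustment. Medians were -0.10 for 25 genes of glia and Schwann cell precursors (adjusted p = 0.284), -0.11 for 22 of endothelium and pericytes (0.292), -0.10 for 20 of macrophages (0.186). They were 0.11 for 10 of red cells (0.278), 0.28 for 12 of skeletal muscle (0.125), -0.09 for 13 of cartilage (0.408) and -0.04 for 14 of spinal cord (0.535).

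The lists of sensory neuron subtypes did not pass as lists in vivo, and single members stood out when adjusted over the list alone. Nociceptor identity genes had a median of 0.05 over 21 genes (camera adjusted p = 0.125 with Benjamini-Hochberg adjustment). Of them 1 rose over all genes, Hoxd1, and 4 rose when adjusted over the list alone, Hoxd1, Ret, Etv5 at 0.57 (SE 0.15) and Dpp6 at 0.45 (SE 0.13). Nociceptor channel and receptor genes had a median of -0.003 and a mean of 0.11 over 23 genes (adjusted p = 0.389 in the same test), with 0 called over all genes and 2 higher when adjusted over the list alone, Htr3b and the prostacyclin receptor gene Ptgir at 1.28 (SE 0.21). Proprioceptor and mechanoreceptor genes had a median of -0.19 over 21 genes (adjusted p = 0.0665), with 0 called over all genes. Adjusted over the list alone, 5 of these were lower, including the protocadherin gene Pcdh8 at -0.54 (SE 0.13), the transcription factor gene Shox2 at -0.45 (SE 0.13) and the netrin G1 gene Ntng1 at -0.53 (SE 0.15), and the potassium channel gene Kcna2 was higher at 0.55 (SE 0.17). With the replicate letter as a block none of these 6 calls was kept, nor was that of Dpp6.

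The remaining neuronal and signalling lists did not pass in vivo either. Pan-neuronal genes had a median of 0.10 over 31 genes (camera adjusted p = 0.131 with Benjamini-Hochberg adjustment), with Rbfox3 at 0.70 (SE 0.17) and Avil at 0.67 (SE 0.15) higher when adjusted over the list alone. Axon growth genes had a median of 0.03 over 30 genes (0.389), axon guidance genes -0.11 over 38 (0.125), and synaptic vesicle genes -0.04 with a mean of 0.01 over 29 (0.655). In these 3 lists the Eph receptor gene Epha3 at -0.84 (SE 0.17) was the 1 member lower when adjusted over the list alone. It was not called with the replicate letter as a block. Targets and feedback genes of ERK signalling had a median of 0.07 over 28 genes (0.306), with 1 member, Jun, lower when adjusted over the list alone at -0.83 (SE 0.15). Cell death genes had a median of -0.06 over 24 genes (0.389), with Hrk and the p53 target gene Trp53inp1 at -0.58 (SE 0.15) lower when adjusted over the list alone. Of these, Hrk alone was kept with the replicate letter as a block. Amino acid and ER stress genes had a median of 0.01 and a mean of -0.01 over 32 genes (0.807), and cytoskeletal targets of SRF -0.09 over 27 (0.204).

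**Figure D2:**
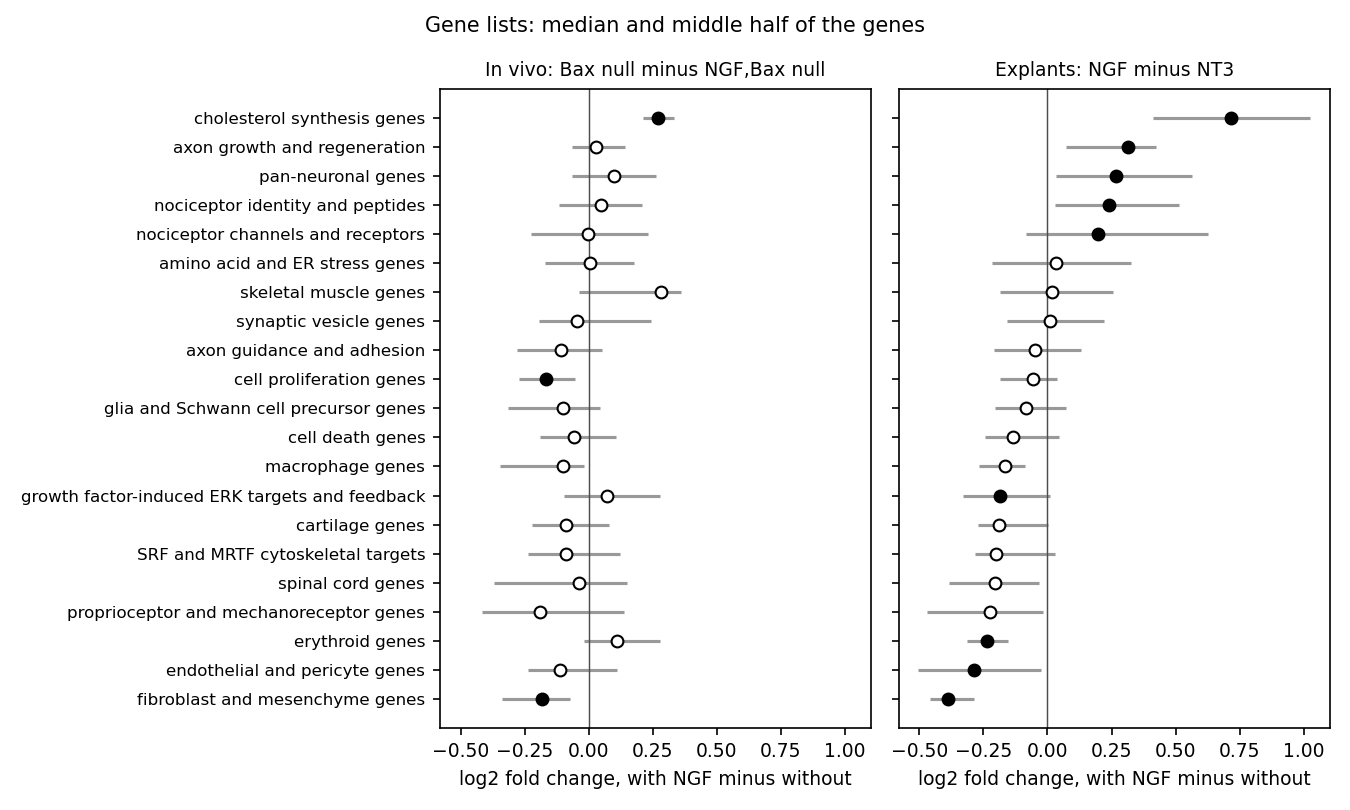
Median log2 fold change (points) and interquartile range (grey lines) of 21 gene lists, with NGF minus without, in ganglia in vivo on the left and in explants on the right. Filled points passed camera with the preset correlation, 3 lists in vivo and 9 in the explants, and cholesterol synthesis genes had the highest explant median, 0.72.

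The explant comparison asked which transcripts differ between ganglia grown with NGF and with NT3. These ganglia were wild type, so a loss of NGF-dependent neurons with NT3 was not separated from a change of expression. Cartpt, which encodes the neuropeptide precursor CART, fell by 3.46 on the log2 scale with NGF (SE 0.26, n = 2), from a mean signal of 505.0 with NT3 to 31.7, by its probe set on chip 2. With the culture number as a block, Hoxd1 rose by 1.62 (SE 0.33), from 33.8 to 137.8. The sterol synthesis gene Msmo1 rose by 1.45 and the synaptic vesicle calcium sensor gene Syt1 by 1.53, while the complexin gene Cplx1 fell by 1.59, from 521.7 to 155.2. The cell surface protein gene Thy1 fell from 177.0 to 8.67, below the lowest mean tested, so the size of its change is uncertain. Genes of cholesterol synthesis, axon growth, neurons and nociceptors were higher with NGF as lists, and genes of fibroblasts, endothelium and ERK signalling were lower. None of these lists passed camera with an estimated correlation (adjusted p from 0.246 to 0.277, Benjamini-Hochberg), a form that also missed the planted shifts in simulated arrays.

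Without a block, 2 of the 22021 probe sets passed in limma with Benjamini-Hochberg adjustment, Cartpt on chip 2 and a probe set of Ptgds, which encodes a prostaglandin D synthase, both at adjusted p = 0.0480. An unadjusted p under 0.05 was reached by 755 probe sets, where chance would give 1101. The fold change of Cartpt was -3.39 within culture number 1 and -3.52 within number 2, and a Cartpt probe set on chip 3 stood at 0.23 (SE 0.43, adjusted p = 1.00). This Ptgds probe set, named after its values were seen, stood at 2.39 (SE 0.22) and another Ptgds probe set at 2.19 (SE 0.23, adjusted p = 0.0969). The Ptgds probe set that the naming rule selects stood at -0.01 (SE 0.22, adjusted p = 1.00). With 1 array left out, the count of calls was 3 without NGF culture 1, 6 without NGF culture 2, 15 without NT3 culture 1 and 21 without NT3 culture 2. Cartpt did not pass without NT3 culture 1 (adjusted p = 0.0881, against 1.23e-04 to 0.158 over all its settings, with limma and Benjamini-Hochberg adjustment). No probe set passed without the filter, with quantile scaling or in eBayes without a trend.

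The explant arrays split by culture number more than by neurotrophin. With the number as a block 176 probe sets passed, 96 higher and 80 lower with NGF. The 2 calls made without the block were among them. The block calls lay on chips 1, 2 and 3 in the numbers 133, 32 and 11. By the probe set that the naming rule selects, the 10 highest genes were Gchfr at 1.87 (SE 0.31), Ly86 at 1.66, Hoxd1 at 1.62, Rgs4 at 1.59, Syt1 at 1.53, Serpinb2 at 1.51, Idi1 at 1.69 and 1.31 within numbers 1 and 2, Msmo1 at 1.45, the cannabinoid receptor gene Cnr1 at 1.44 and the diacylglycerol kinase gene Dgkh at 1.43. The 10 lowest were Cartpt, Thy1 at -2.70 (SE 0.56), AI593442 at -2.69, Plek2 at -2.22, AW551984 at -2.15, Cntnap1 at -2.09, Ppm1h at -2.07, C1qtnf4 at -1.88, 2700046A07Rik at -1.85 and Chchd10 at -1.71. Probe sets that the rule does not select lay higher for Med15 (2.54), Ptgds (2.39 and 2.19) and Dhx29 (1.96) and fell as far as the 10 lowest for 4833439L19Rik and Taf1d. Changes were smaller by other probe sets of Syt1 (0.96, which passed with the block, and 0.71, which did not), and by others that did not pass of Msmo1 (0.69), Idi1 (1.09), Dgkh (1.05) and Ppm1h (-0.82). The lower group mean of Cartpt, Thy1, AI593442, Cntnap1, C1qtnf4, Hoxd1 and Serpinb2, and of Runx1 and Car2 named below, lay under the lowest mean tested on its chip, so the sizes of these changes are uncertain. Within culture numbers 1 and 2, Hoxd1 stood at 1.57 and 1.67, Syt1 at 1.43 and 1.63, Thy1 at -3.47 and -1.92, and Cplx1 at -2.05 and -1.13. For Hoxd1 the limma adjusted p with Benjamini-Hochberg adjustment was 0.746 without the block and 4.64e-04 with it, and for Syt1 it was 0.554 and 1.43e-06. The neurotrophin receptor genes did not pass in either fit, with Ntrk2 at -0.22 (SE 0.30), Ntrk3 at -0.23 (SE 0.37) and Ngfr at 0.03 (SE 0.22).

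**Figure D3:**
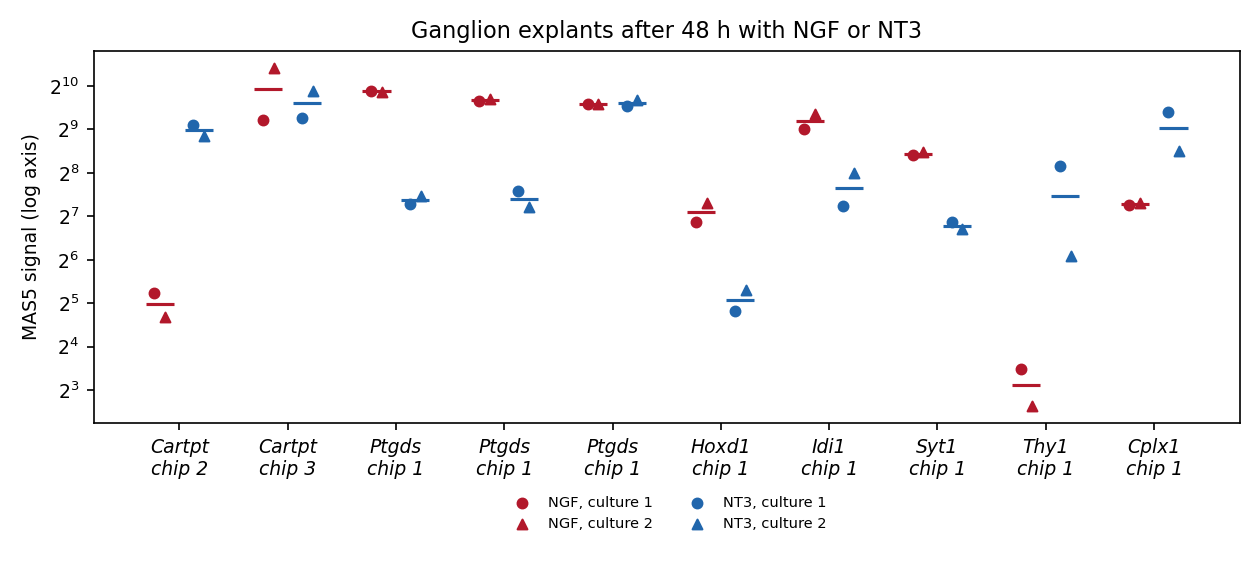
MAS5 signal on a log axis of 10 probe sets in ganglion explants after 48 h with NGF (red) or NT3 (blue), with circles for culture 1, triangles for culture 2 and bars for the mean of 2 cultures; the chip that holds each probe set stands under its gene. The chip 2 probe set of Cartpt falls from a mean of 505.0 to 31.7 with NGF while the chip 3 probe set has means of 782.0 and 980.1. The 3 Ptgds probe sets, all on chip 1, disagree too. Those with means of 165.7 and 169.5 with NT3 rise to 937.0 and 823.1 with NGF, and the other has means of 774.9 and 770.4.

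Cholesterol synthesis genes were higher with NGF in the explants as well. Of 19 measured members 18 lay above 0, with a median of 0.72 (0.68 and 0.73 within culture numbers 1 and 2) and a camera adjusted p of 9.63e-19 with Benjamini-Hochberg adjustment (adjusted p = 0.246 with an estimated correlation). No member passed over all genes without the block, 8 rose when adjusted over the list alone, and 11 rose over all genes with the block. Among them were Cyp51 at 1.23 (SE 0.31), the lanosterol demethylase, Lss at 1.07 (SE 0.31), the lanosterol synthase, and Fdps at 0.98 (SE 0.27), the farnesyl diphosphate synthase.

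**Figure D4:**
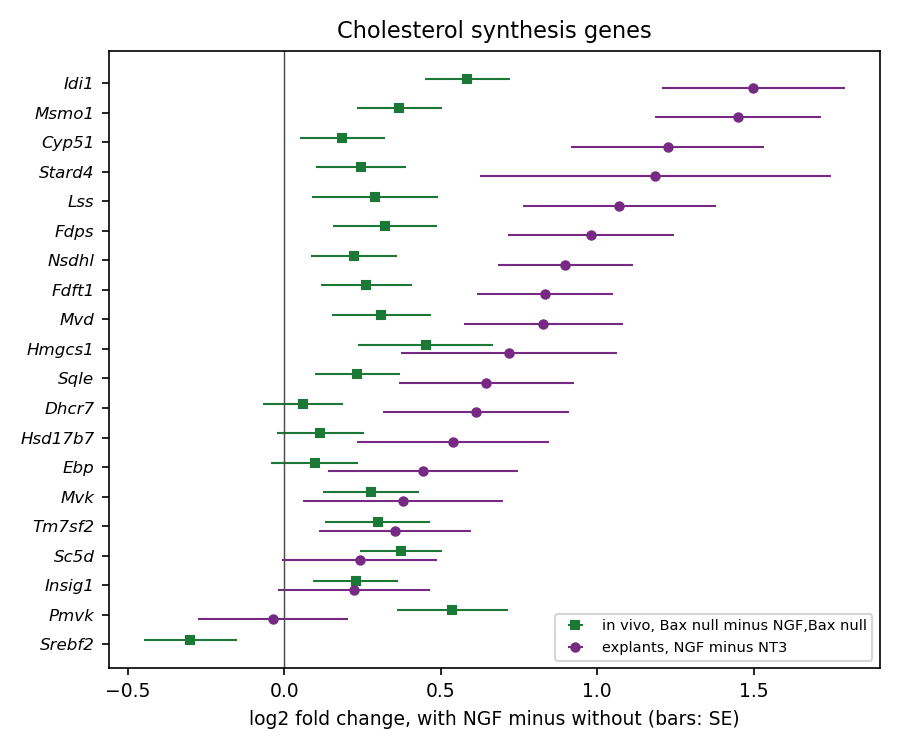
Log2 fold change of each measured cholesterol synthesis gene, with NGF minus without, with squares for ganglia in vivo, circles for explants and bars for the SE of 2 samples per group. In vivo 19 of 20 genes lie above 0 and in the explants 18 of 19, led in vivo by Idi1 at 0.59, while Srebf2 lies at -0.30 in vivo.

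Genes of neurons and axons were higher with NGF in the explants as lists. Axon growth genes had 24 of 28 members above 0 and a median of 0.32 (0.23 within each culture number, and 0.15 without NGF culture 1). It had a camera adjusted p of 8.60e-06 with Benjamini-Hochberg adjustment (adjusted p = 0.246 with an estimated correlation; between 4.61e-07 and 0.0215 over 13 other settings). No member passed over all genes or when adjusted over the list alone. With the block 5 rose, including Dpysl3 at 0.69, Crmp1 at 0.67 and the microtubule protein gene Dcx at 0.62. Pan-neuronal genes had 22 of 29 members above 0 and a median of 0.27 (0.24 and 0.41 within numbers 1 and 2; camera adjusted p = 5.31e-05 with Benjamini-Hochberg adjustment, adjusted p = 0.246 with an estimated correlation). None passed over all genes, and adjusted over the list alone Syt1 and the transcription factor gene Pou4f1, at 0.85 (SE 0.21), rose and Thy1 fell. With the block 4 rose, including Isl1 at 1.10 (SE 0.39) and Celf4 at 0.81 (SE 0.26), and Thy1 and Avil, at -1.09 (SE 0.30), fell. The pan-neuronal list did not pass without NGF culture 2 (adjusted p = 0.0522) or NT3 culture 2 (0.0524), against 9.43e-08 to 0.0524 over 13 other settings of camera with Benjamini-Hochberg adjustment.

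Nociceptor genes were higher with NGF as lists in the explants, where a loss of nociceptors with NT3 could also give this direction. Nociceptor identity genes had 14 of 18 members above 0 and a median of 0.24 (0.32 and 0.17 within numbers 1 and 2; camera adjusted p = 2.84e-04 with Benjamini-Hochberg adjustment, adjusted p = 0.246 with an estimated correlation). None passed over all genes, Hoxd1 rose when adjusted over the list alone, and with the block Hoxd1 and Runx1, a transcription factor gene of nociceptor subtypes, at 1.30 (SE 0.39), rose. Nociceptor channel and receptor genes had 8 of 11 members above 0 and a median of 0.20 (0.11 and 0.22 within numbers 1 and 2; camera adjusted p = 0.0140 with Benjamini-Hochberg adjustment, adjusted p = 0.277 with an estimated correlation). None passed over all genes, and both adjusted over the list alone and with the block 2 rose, Cnr1 and the sodium channel gene Scn10a at 1.11 (SE 0.29). The channel list did not pass without NGF culture 1 (median 0.06, adjusted p = 0.0621) or NGF culture 2 (median 0.01, adjusted p = 0.0807), and its median was -0.009 without the filter on low values (adjusted p = 0.978). Over 13 other settings its camera adjusted p with Benjamini-Hochberg adjustment lay between 7.09e-04 and 0.978. Proprioceptor and mechanoreceptor genes did not pass (median -0.23 over 18 genes, -0.27 and -0.23 within numbers 1 and 2, adjusted p = 0.158), with 0 called over all genes or when adjusted over the list alone. With the block Pvalb, at -0.70 (SE 0.26), and Nefh, at -0.86 (SE 0.38), fell.

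Fibroblast and mesenchyme genes were lower with NGF in the explants, with 23 of 25 members below 0 and a median of -0.39 (-0.35 and -0.36 within numbers 1 and 2; camera adjusted p = 8.64e-07 with Benjamini-Hochberg adjustment, adjusted p = 0.246 with an estimated correlation). None passed over all genes or when adjusted over the list alone, and 4 fell with the block, the collagen VI genes Col6a1 at -0.76, Col6a2 at -0.60 and Col6a3 at -0.56 and the growth factor receptor gene Pdgfra at -0.66. Endothelial and pericyte genes had 13 of 18 members below 0 and a median of -0.29 (-0.10 and -0.39 within numbers 1 and 2; camera adjusted p = 0.00315 with Benjamini-Hochberg adjustment, adjusted p = 0.271 with an estimated correlation). None passed over all genes or over the list alone, and Emcn, at -0.97 (SE 0.26), fell with the block. The endothelial list did not pass without NGF culture 2 (adjusted p = 0.0807) or NT3 culture 2 (median -0.16, adjusted p = 0.0604), against 0.00122 to 0.0807 over 13 other settings. Genes of glia and Schwann cell precursors had a median of -0.08 over 22 genes and did not pass (adjusted p = 0.487).

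Targets and feedback genes of ERK signalling, a pathway that neurotrophins activate, were lower with NGF than with NT3 as a list, with 23 of 31 members below 0 and a median of -0.18 (-0.27 and -0.26 within numbers 1 and 2; camera adjusted p = 0.0140 with Benjamini-Hochberg adjustment, adjusted p = 0.271 with an estimated correlation). None passed over all genes or over the list alone, and 1 fell with the block, Ier3 at -0.64 (SE 0.51), while Jun stood at -0.77, Spry2 at -0.66 and Fos at -0.57. The list did not pass without NGF culture 2 (median -0.12, adjusted p = 0.181), without NT3 culture 1 (median -0.16, adjusted p = 0.217) or with the mean over probe sets (adjusted p = 0.0870). Its median was -0.34 without NGF culture 1 and -0.30 without NT3 culture 2. Over 13 other settings its camera adjusted p with Benjamini-Hochberg adjustment lay between 8.82e-04 and 0.217.

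Red cell genes, the erythroid genes list, all lay below 0, 10 of 10, with a median of -0.23 (-0.32 and -0.22 within numbers 1 and 2; camera adjusted p = 0.0473 with Benjamini-Hochberg adjustment, adjusted p = 0.478 with an estimated correlation). Of these 0 passed over all genes and 1 fell both adjusted over the list alone and with the block, Car2 at -1.53 (SE 0.39), a carbonic anhydrase gene that sensory neurons also express. The median was 0.06 without NGF culture 2 (adjusted p = 0.631), 0.10 without NT3 culture 1 (adjusted p = 0.563), -0.49 without NGF culture 1 and -0.59 without NT3 culture 2. The list passed in 7 of 13 other settings and also did not pass with a pseudocount of 64 (adjusted p = 0.0504), without the filter (0.0548), in the highest 40% (0.282) or with median scaling (0.0828). The camera adjusted p with Benjamini-Hochberg adjustment lay between 7.63e-04 and 0.631 over 13 other settings. The other explant lists did not pass and had medians between -0.20, for 11 spinal cord genes, and 0.03, for 32 amino acid and ER stress genes. These included macrophage genes at -0.17, proliferation genes at -0.06, skeletal muscle genes at 0.02, cartilage genes at -0.19, cell death genes at -0.13, SRF targets at -0.20, axon guidance genes at -0.05 and synaptic vesicle genes at 0.01. Of these lists the synaptic vesicle genes held 1 member that fell when adjusted over the list alone, Cplx1, whose 2 probe sets both fell with the block. With the block Syt5 of the same list rose, at 0.79, and of the other lists Cntn1 of axon guidance, at 0.87, and Atf4 of ER stress, at 0.57, rose, while the semaphorin receptor gene Plxnd1 of axon guidance fell, at -0.77.

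The comparison of the screens asked whether genes moved alike with NGF in vivo and in culture. Only the in vivo ganglia lacked Bax, so a shared direction can reflect neuron survival in the explants. Hoxd1 was higher with NGF in both, by 2.27 in vivo and 1.62 in the explants, and it passed in both once the explants were fitted with the culture number as a block. No gene passed in both screens without the block, with 1 gene called in each among the 10129 genes tested in both (Fisher's exact test, p = 1). With the explant block, 1 and 116 of these genes were called and 1, Hoxd1, was shared (Fisher's exact test, p = 0.0115). As only 1 gene was called in vivo, this p is just the share of genes called in the explants. It gives no measure of how far the screens overlap. Across these genes, which are not independent replicates, the log2 fold changes correlated at Pearson's r of 0.13 and Spearman's rho of 0.14, and 55.4% had the same sign. The correlation was 0.0574 without NT3 culture 2 and 0.0848 without NGF culture 1. An unadjusted p under 0.05 in both screens was reached by 59 genes, against 28.7 for independent lists, and 50 of these had the same direction. Higher in both were 34, against 5.93 for independent lists, and lower in both were 16, against 8.49.

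Named from this overlap after their values were seen, Rgs7 stood at 1.01 in vivo and 1.08 in the explants, Tmtc1 at 1.13 and 1.02, Rgs4 at 0.66 and 1.59, Ly86 at 0.78 and 1.66, Chst15 at 0.89 and 0.93, Antxr2 at 0.74 and 0.86, and Ptgir at 1.28 and 1.01. On the lower side the annexin gene Anxa1 stood at -0.92 in vivo and -1.07 in the explants, and Jun at -0.83 and -0.77. None of these genes passed in limma with Benjamini-Hochberg adjustment in either screen without the block. The difference between the screens, tested in the joint fit, passed for 1 gene, Cartpt, which stood at 0.77 in vivo and -3.46 in the explants (adjusted p = 0.00210 with Benjamini-Hochberg adjustment). In that fit 396 genes had an unadjusted p under 0.05, where chance would give 506. With the explant culture number as a block 9 genes passed, Cartpt, Ppm1h, Avil, Cplx1, Chchd10, Hapln3, Hs3st2, AI593442 and 2700046A07Rik, each lower with NGF in the explants than in vivo.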

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

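Of the tests below, those of the neuron share, of a loss of NGF-dependent neurons and of the share of non-neuronal cells were chosen after the list results were seen, and the joint fit of both screens was not among the tests fixed before the data were examined. The effect of NGF differed between the screens for 1 gene and 4 lists, in vivo minus explants. For Cartpt the difference of log2 fold changes was 4.23 (SE 0.31, adjusted p = 0.00210 in limma with Benjamini-Hochberg adjustment), and the groups did not overlap in either screen, although the chip 3 probe set of the gene stood at 0.23 in the explants. By camera with Benjamini-Hochberg adjustment, the median difference was -0.52 for cholesterol synthesis genes (adjusted p = 8.08e-07), -0.25 for axon growth genes (0.00642), 0.27 for ERK targets (0.00972) and -0.18 for pan-neuronal genes (0.0294). With an estimated correlation none of these 4 differences passed (adjusted p = 0.241, 0.355, 0.241 and 0.303). With the explant culture number as a block 9 genes differed, Cartpt among them, and the red cell list passed beside the 4 lists (adjusted p = 0.0301 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.452 with an estimated correlation, without the block). The screens differ in array type, age, culture, genotype and the comparison group, none of which was tested on its own.

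Cholesterol synthesis genes were higher with NGF in both screens, though not with an estimated correlation (camera adjusted p = 0.542 in vivo and 0.246 in the explants, Benjamini-Hochberg), which the tests below, on single genes permuted or drawn, leave out of account. A larger share of neurons in the RNA would raise pan-neuronal genes. The cholesterol list lay above the pan-neuronal list in vivo (medians 0.27 and 0.10, one-sided permutation p = 0.00807) and in the explants (0.72 and 0.27, permutation p = 0.0106). The comparison with this list cannot decide, because pan-neuronal members went both ways, with 21 of 31 above 0 in vivo and 22 of 29 in the explants. Rbfox3 at 0.70 and Avil at 0.67 in vivo lay above the cholesterol median. So did Syt1 at 1.53 and Pou4f1 at 0.85 in the explants, where Thy1 stood at -2.70. The neuron share therefore stays open. A dependence of fold change on signal level left by the scaling is argued against. The cholesterol median exceeded all 10000 random lists matched on mean signal in both screens (percentile 100 in each). The higher actin 3' to 5' ratio of NT3 culture 1 is argued against too. The median in the culture number 2 pair, 0.73, was also at percentile 100. Loss of NGF-dependent neurons from the wild-type NT3 cultures would lower nociceptor genes there. The cholesterol list lay above the 29 genes of both nociceptor lists (median 0.22, one-sided permutation p = 0.00409). This comparison cannot decide, because nociceptor members went both ways, with 14 of 18 and 8 of 11 above 0. Hoxd1 at 1.62, Cnr1 at 1.44 and Scn10a at 1.11 lay above the cholesterol median, so such a loss stays open. An effect of NGF on sterol synthesis in ganglion cells may underlie the pattern, as a hypothesis found and tested on the same arrays.

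Fibroblast and mesenchyme genes were lower with NGF in both screens, though not with an estimated correlation (camera adjusted p = 0.542 in vivo and 0.246 in the explants, Benjamini-Hochberg). If the RNA merely held a smaller share of all non-neuronal cells, glial genes would fall alike. In the explants the glial median of -0.08 lay above the fibroblast median of -0.39 (one-sided permutation p = 1e-05, the smallest the 100000 permutations can give), which argues against an equal loss of all non-neuronal cells there. Other explant lists went along with the fibroblast genes, endothelium at -0.29, red cells at -0.23 and macrophages at -0.17 against pan-neuronal genes at 0.27, so a smaller share of non-neuronal cells other than glia stays open. In vivo the medians were -0.10 and -0.18 (permutation p = 0.132), so a smaller non-neuronal share cannot be told apart from a change of fibroblasts alone, because the medians lie too close for the spread of 25 glial genes; how much connective tissue was dissected or grew was not tested in either screen.

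The explant arrays split by culture number more than by neurotrophin, and the groups do not explain this, so no biological explanation was tested. Hybridisation or scanning of single arrays as the whole cause is argued against only narrowly, and for chips 1 and 2 only. For 1106 genes with probe sets on both, the number 1 minus number 2 difference correlated between the chips at r = 0.2005. The 95% interval was 0.143 to 0.257, across genes, which are not independent. This r only just reached the bound of 0.2 set beforehand for arguing against that cause. With signal level removed it was 0.195, under that bound. The correlation was 0.0868 between chips 1 and 3 and 0.0801 between chips 2 and 3. Both lay under the other bound set beforehand, the sign of a cause in single arrays. The actin ratio of NT3 culture 1 is argued against as the cause of the split. The spread of the difference in the NT3 pair was at most 1.005 times that in the NGF pair on any chip. That test does not cover hybridisation or scanning runs shared by the arrays of a number. What remains open includes a difference between such runs, cultures, dissections or labelling reactions that shared a number. On chip 1 the highest signal was 18172.2 (NGF) and 19093.4 (NT3) for number 1, against 6907.7 and 6177.7 for number 2. The step at which the difference between the numbers entered was not tested.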

How the results depend on the processing

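The crossed replicate block, the replicate block together with an estimated correlation, and the 2-fold rule on other splits were chosen after seeing the data. The in vivo count of 4 was within 1.5 times with a pseudocount of 1 or 64 (4 and 4), quantile scaling (6) and median scaling (5), each sharing all 4 calls. It was 0 without the filter (3158 at unadjusted p under 0.05), 0 in eBayes without a trend (2048), 10 in the highest 40%, 2 with the replicate block and 22 by the 2-fold rule, which has no p; with single replicates left out it ran from 16 to 2103, with the lone array assumed to vary like the other group. The in vivo letters are not paired by the labels, and a crossed replicate block (Bax null A with NGF,Bax null B) called 604, 290 higher and 314 lower. The explant count of 2 stayed at 2 with a pseudocount of 1 or 64, the highest 40% and median scaling, and was 3 with adjustment within each chip. It was 0 without the filter (1203 at unadjusted p under 0.05), 0 with quantile scaling (765), 0 without a trend (790), 176 with the replicate block and 111 by the 2-fold rule, and from 3 to 21 with single cultures left out. By the 2-fold rule, splitting the 4 arrays by crossed letters gave 25 in vivo and by letter 6, and splitting the explants by culture number gave 351 and by crossed numbers 48, so a split other than the real one gave as many in both screens; this points to a structure of the arrays, and 176 is the blocked explant value. Of the lists, 3 in vivo became 0 with the estimated correlation, 0 with it and the replicate block together, 5 with the mean over probe sets, and 3 to 6 with replicates left out; 9 in the explants became 0, 0, 8 and 4 to 8. The replicate block left all 12 list calls in place and added the pan-neuronal list in vivo (adjusted p = 0.0356 by camera with Benjamini-Hochberg adjustment); it ended the calls of Tbx18 and Cdkl4, and, adjusted over the list alone in vivo, those of all 6 proprioceptor genes, Dpp6, Epha3, Trp53inp1 and Idi1. Across 13 settings without an estimated correlation, cholesterol, fibroblast, axon growth and nociceptor identity lists passed in all, in each screen where they had passed. The correlation of the screens, 0.128, was 0.0819 without the filter, 0.160 in the highest 40% and 0.0574 to 0.151 with replicates left out; over genes called in either screen there were 2, too few for a correlation. Reversed were the explant median of nociceptor channels without the filter (-0.009325), that of red cell genes with single cultures left out (-0.59 to 0.10), and probe sets of Cartpt (0.23) and Ptgds (2.39, against -0.01). Fewer tested probe sets ease the adjustment in the highest 40%; the cause of the other shifts was not tested. Signals near background limit weak genes: the lowest mean tested was 30.04 in vivo, against a median signal of 46.2 to 51.1.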

Other observations

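The list of neurogenesis genes and the tests below were chosen after the in vivo fold changes had been seen. Among genes lower with NGF in vivo were several transcription factors of early neuron differentiation, none past the threshold over all genes: Lhx2 at -2.11 (SE 0.25), Neurod6 at -1.04 (SE 0.18), Insm1 at -0.95 (SE 0.16), Neurod1 at -0.92 (SE 0.15) and Nhlh1 at -0.87 (SE 0.14). Of 31 measured neurogenesis genes 22 lay below 0, with a median of -0.34, and Dll3 was an exception at 0.67. Of the 25 genes whose own values had not been seen, 16 lay below 0, with a median of -0.21. This is the direction predicted if NGF lowers this programme of early neuron differentiation. Limma camera gave p = 6.77e-04 (n = 25 genes) and p = 0.0650 with an estimated correlation. These genes were picked for the same programme and read from the same arrays, so they give no independent test of that hypothesis. In the explants 19 neurogenesis genes, without Myt1 whose value of 1.11 had been seen, had a median of -0.07, with limma camera pointing upward (camera p = 0.596, n = 19 genes compared with all others, not independent of each other). The bound set beforehand, a p of 0.05 or more or an upward direction, was wrong as a ground for exclusion. A missed threshold shows no absence of an effect, and a direction at this p, with a median of the other sign, lies within the spread of the genes.

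The NGF null allele could bring along sequence of another strain around Ngf, which could move neighbouring probe sets. Among the 20 measured genes on each side of Ngf, 17.5% had an unadjusted p under 0.05 in vivo (exact 95% interval 7.34% to 32.8%). This share stood at percentile 95.03 of 12244 windows of 40 neighbouring genes, whose median was 7.5%, and the interval reaches to both sides of the bound, so the explanation stays open for these genes. The neighbours include Vangl1 at 0.62 (SE 0.14), Tspan2 at 0.51 (SE 0.17), Phtf1 at 0.71 (SE 0.16) and the neurogenesis gene Nhlh2 at -0.58 (SE 0.13).

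The sex-linked genes, measured in pooled embryos of mixed sex, were Xist at a mean signal of 716.2 with NGF and 387.2 without (0.86, SE 0.14, adjusted p = 0.136 in limma with Benjamini-Hochberg adjustment), Uty at -0.33, Kdm5d at -0.24 and Eif2s3y at -0.07. Adjusted over the list alone, Xist was called as higher with NGF, with and without the replicate letter as a block. Whether the share of each sex differed between the genotypes was not tested. In the explants 1 sex-linked gene was measured, at 0.21.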
